A study of Mus musculus with 2 samples.

How the data were processed

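Single-cell RNA sequencing libraries were made from myeloid cells of mouse tumour-draining lymph nodes. Per the labels, cells that lacked CD90.2, B220 and NK1.1 and carried CD11c or CD11b were sorted, and per the labels' protocols libraries were made with the 10x Chromium Single Cell 3' V2 kit. There were 2 libraries, 1 from a control (C57Bl/6) and 1 from a Foxp3DTR background, both at day 5 after diphtheria toxin. The human samples that the series' design text mentions were not used here. Per the submitters' processing notes, the reads were processed with Cell Ranger 2.1 and genome build mm10. Per the labels, the raw reads of the Foxp3DTR library could not be uploaded because their file was damaged. The annotation used was not given in the sources used here.

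The deposited matrices hold counts, that is whole-number UMI counts per gene and cell barcode, for 27998 genes. The deposited identifier and barcode lists, of a unit other than counts, name the matrix entries. The authors also deposited dense count tables, which were checked against the sparse matrices. The 14532 genes compared in the control and the 14352 in the Foxp3DTR library had 0 differing values in the cells that both kinds of file hold. The control table has 4470 columns for the 4471 barcodes of its matrix, so 1 control barcode was not compared; the Foxp3DTR table has 5242 of 5242. In the matrices, 121 entries share a symbol with another gene. The control library held 4471 barcodes and the Foxp3DTR library 5242, with between 1627 and 35066 UMIs each, so the files hold no barcode of lower depth.

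Cells with fewer than 500 genes or over 10% mitochondrial UMIs were removed, which took out 11 control and 4 Foxp3DTR cells. Doublet scores were computed by comparing each cell with simulated doublets, as in Scrublet. The highest-scoring cells were removed at an expected rate of 0.8% per 1000 cells, which took out 159 control cells (3.57%) and 219 Foxp3DTR cells (4.18%). This left 4301 control and 5019 Foxp3DTR cells. Counts were scaled to 10000 per cell and log-transformed, and the libraries were clustered together without integration. The 2000 most variable genes, 30 principal components, 20 neighbours and Leiden resolution 1 gave 20 clusters, of which 17 could be named. Clusters were named by 18 marker lists, from the mean log values standardised over clusters. A name needed at least 3 measured markers and a clear lead over the next list. Clusters led by cycling genes were not named. Cells with over 2% of UMIs from neutrophil markers (4 control and 3 Foxp3DTR) were taken out of the classes. That limit, the naming by mean log values and the joint monocyte-like and macrophage-like group were set after seeing the data. Markers of Langerhans cells were not a class of their own.

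For classes with at least 100 cells in each library, UMIs were summed per class and library and expressed per 1000000 UMIs of the class total (CPM). The 4 classes that met this were migratory DC-like, cDC2-like, cDC1-like and monocyte-like cells. Ratios are Foxp3DTR over control, with exact conditional binomial intervals at 95% confidence. Cells of 1 library are not replicates, so no p-value and no number of changed genes was made from them. Class totals in UMIs were 16452170 and 19669967 for migratory DC-like cells, 3401470 and 3604439 for cDC2-like cells, 1830870 and 1732028 for cDC1-like cells, and 1404406 and 4929489 for monocyte-like cells, control first. A 0 was treated as compatible with up to 3 counts.

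The 15 gene lists, the marker lists and the rule for named genes were fixed before the data were examined. The lists cover costimulation, migration and chemokines, MHC class I and II, type I and gamma interferon, immunoregulation, inflammatory cytokines, the interleukin-4, interleukin-13 and GM-CSF response, cell cycle, glycolysis, oxidative phosphorylation, immediate early and heat shock genes, mitochondrially encoded genes and regulatory T cells. Some genes, Ccl17 among them, are in more than 1 list. List members needed at least 20 UMIs over both libraries in the class. Each list's median log2 ratio was placed among 10000 random lists of the same size, drawn from 20 expression bins. The named genes of each class are the 10 with the highest and the 10 with the lowest ratio among genes with at least 50 UMIs and at least 100 CPM in 1 library. Mitochondrial, ribosomal protein, haemoglobin and immunoglobulin genes and unnamed gene models were left out. To these come the highest and lowest member of each list described, and Foxp3. Positions are from GENCODE M21. In the lists 1 gene, and among the markers 9, had no entry in the files.

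On simulated data with known changes, counts were drawn for classes of the largest and the smallest compared size. With 3000 cells per library, the intervals lay on the right side of 1 for 98.5% of genes changed by 2 times. With 150 cells they did so for 83.8%. They held the true ratio for 95.3% and 95.6% of unchanged genes. The simulated counts were Poisson sums without spread between cells, which is what the intervals assume. These shares therefore check the calculation, and not how well the intervals cover counts of real cells.

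Alternatives fixed beforehand were other Leiden resolutions, stricter and looser cell filters, doublets kept, each library clustered on its own, cells thinned to 3000 UMIs (497 control and 287 Foxp3DTR cells were shallower and left out), other scalings of the ratios and other minimum counts for list members. Other cell filters, kept doublets and thinning were each followed by new clustering and naming, so the cells of a class could change. Alternatives chosen after seeing the data were clusters weighted alike in both libraries, clustering without the listed and named genes, monocyte-like and macrophage-like cells joined, and each gene without its top cell (for Ccl17 also within clusters). Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.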

Results

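Droplet-based single-cell RNA sequencing was used to compare myeloid cells of tumour-draining lymph nodes between control mice (C57Bl/6) and Foxp3DTR mice. In the latter, a diphtheria toxin receptor fused to GFP is knocked into Foxp3, the gene of the transcription factor that defines regulatory T cells, so that diphtheria toxin (DTx) removes these cells. The mice carried B16-F10 tumours, a transplantable mouse melanoma line, and nodes were taken on day 5 after DTx. The comparison addresses how dendritic cells (DCs) and other myeloid cells of the node differ once regulatory T cells are depleted. There was 1 library per genotype, so no difference could be tested against the spread between animals. The 95% intervals given here cover counting error only, and values are described as higher or lower in these 2 libraries. The control library held 26855678 unique molecular identifiers (UMIs) and the Foxp3DTR library 38014145. After filtering, the median cell had 5445 UMIs and 1598 genes in the control library and 6536 UMIs and 1832.5 genes in the Foxp3DTR library, with median mitochondrial shares of 1.66% and 1.69%. Foxp3 (chromosome X, 7573644 to 7595245) had 4 UMIs in the control library and 0 in the Foxp3DTR library. The sort selected against T cells, and the lymphocytes that passed it, a cluster of 27 control and 20 Foxp3DTR cells led by Cd79a, Ms4a1 and other B and T cell genes, had 0 Foxp3 UMIs. The count therefore does not measure the depletion.

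Migratory DC-like cells, recognised by Ccr7, Fscn1, Ccl22 and related markers, made up most of both libraries. They were 69.7% of control cells (2996 of 4301, interval 68.3% to 71%) and 60.7% of Foxp3DTR cells (3047 of 5019, 59.3% to 62.1%). Monocyte-like cells were 6.81% of control cells (6.08% to 7.61%) and 14.6% of Foxp3DTR cells (13.7% to 15.6%), a ratio of 2.15 (1.8 to 2.57). This class joined clusters that went in opposite directions. That led by Ms4a6d and Klra2 held 42 control and 681 Foxp3DTR cells, and that led by Hp and Chil3 held 255 and 56. Macrophage-like cells, led by the complement genes C1qa, C1qb and C1qc, were 2.19% (1.77% to 2.67%) and 6.2% (5.55% to 6.9%), a ratio of 2.84 (2.08 to 3.9). The conventional type 2 class, cDC2-like and led by Cd209a, was 12.4% (11.4% to 13.4%) and 9.6% (8.8% to 10.5%). Its ratio of 0.773 (0.655 to 0.913) was 0.931 at Leiden resolution 0.5 and 0.956 with each library clustered on its own. The conventional type 1 class, cDC1-like and led by Xcr1 and Clec9a, was 3.84% and 2.97%, with a ratio of 0.774 whose interval (0.565 to 1.06) includes 1. Basophil or mast cell-like cells numbered 38 and 23, plasmacytoid DC-like cells 7 and 12, and stromal or endothelial cell-like cells 26 and 14. Unnamed clusters held 3.35% of control and 4.86% of Foxp3DTR cells. The surface markers used in the sort set which cells could be counted, so the shares describe the sorted fraction and not the node. Exact Clopper-Pearson intervals were used for shares, and the interval of a ratio spans the values that both allow.

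**Figure D1:**
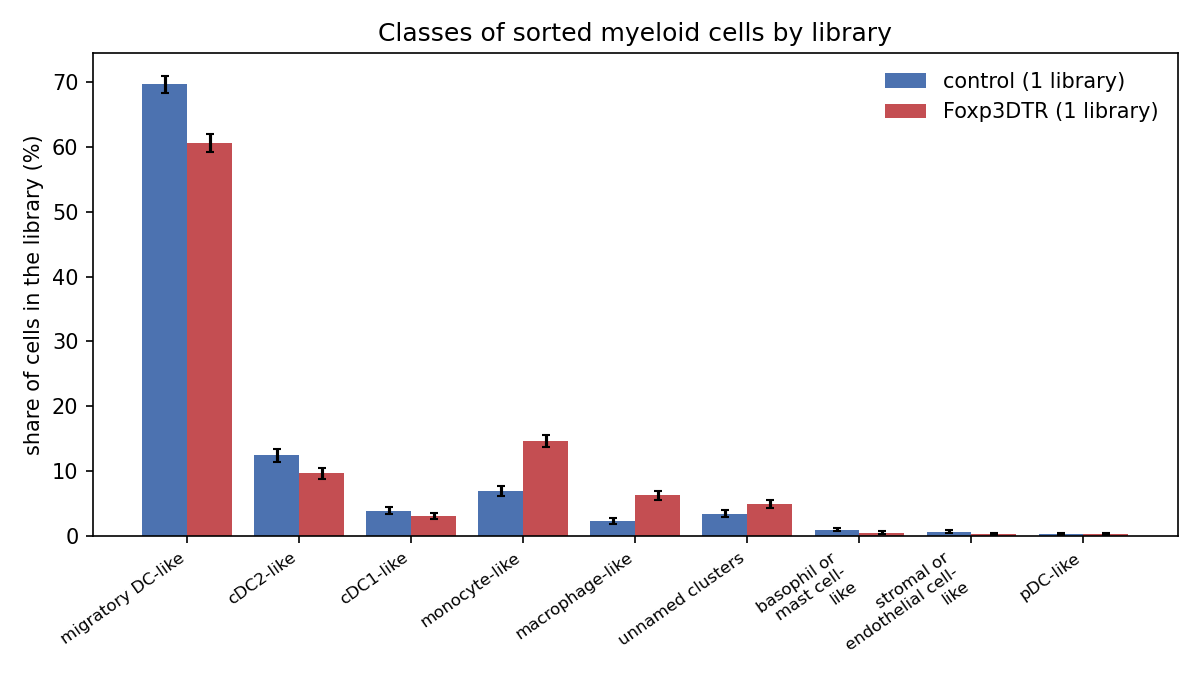
Share of cells (percent, axis from 0) in each cell class of the control and the Foxp3DTR library, with bars for the single library per genotype and error bars for exact 95% binomial intervals. Monocyte-like cells were 6.81% of control and 14.6% of Foxp3DTR cells, and migratory DC-like cells 69.7% and 60.7%. The monocyte-like class joined clusters that went in opposite directions.

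In migratory DC-like cells, Ccl17, a chemokine that attracts T cells through the receptor CCR4, was 547 UMIs per 1000000 UMIs of the class (CPM) in the control and 2496 CPM in the Foxp3DTR library, a ratio of 4.57 (4.47 to 4.67). Pkib, an inhibitor of protein kinase A, was 35.01 and 263 CPM (ratio 7.53, 6.90 to 8.22). Ramp3, a partner protein of the calcitonin receptor-like receptor, was 38.5 and 246 CPM (ratio 6.38, 5.88 to 6.95). Cd80, a ligand of the T cell costimulatory receptor CD28, was 32.7 and 114 CPM (ratio 3.47, 3.16 to 3.82). Stat4, a transcription factor downstream of interleukin-12, was higher by a ratio of 3.67, and the cyclin gene Ccnd2 by 3.55. AA467197 (4.83), Slc27a3 (4.64), Got1 (3.62) and Cytip (3.19) complete the 10 genes named as highest. This ranking holds within the limits for named genes, at least 50 UMIs and at least 100 CPM in 1 library. The libraries filled the clusters of this class unequally: the cluster led by Zmynd15 and Laptm4b held 793 control and 110 Foxp3DTR cells, that led by Ltc4s, Ccl17 and Fxyd2 held 586 and 123, that led by Il12b and Fgfbp3 held 83 and 441, and that led by Ccl17, Gm13546 and Ramp3 held 15 and 277. Within the last of these, the ratio of Ccl17 was 5.10 (4.39 to 5.94), while those of Ramp3 (1.02, 0.757 to 1.41) and Cd80 (0.865, 0.513 to 1.57) had intervals that include 1. Weighting the clusters of the class alike, without that cluster, a setting chosen after seeing the data, lowered several of these log2 ratios: Pkib from 2.91 to 2.17, Ramp3 from 2.67 to 1.82, AA467197 from 2.27 to 1.29, Ccnd2 from 1.83 to 0.98, Stat4 from 1.87 to 1.18 and Cd80 from 1.80 to 1.21.

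Genes lower in Foxp3DTR migratory DC-like cells included Klf2, a zinc-finger transcription factor, at 1051 CPM in the control and 205 CPM in the Foxp3DTR library (ratio 0.195, 0.188 to 0.201). Cxcl1, a chemokine for neutrophils, was 488 and 84.3 CPM (ratio 0.173, 0.164 to 0.182). Icosl, the ligand of the T cell receptor ICOS, was 130 and 31.3 CPM (ratio 0.241, 0.220 to 0.264). Fos and Fosb, immediate early genes of the AP-1 factor, had ratios of 0.385 and 0.311. The other genes among the 10 lowest within the same limits were Tmem158 (0.200), Fxyd2 (0.297), Mfge8 (0.334), the heat shock gene Hspa1a (0.346) and Clu (0.385). Hspa1a has a near-identical neighbour, Hspa1b, so reads can be shared between them. With clusters weighted alike, the log2 ratio of Cxcl1 went from -2.53 to -1.74, that of Fxyd2 from -1.75 to -0.98, that of Mfge8 from -1.58 to -0.70 and that of Hspa1a from -1.53 to -0.70.

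Ccl17 lies on chromosome 8 (94810453 to 94812036) and Klf2 on the same chromosome (72319033 to 72321656), in the GENCODE M21 annotation of the mouse genome. Ly6a lies on chromosome 15 (74994877 to 74998031), Cd80 on chromosome 16 (38455561 to 38496335) and Icosl on chromosome 10 (78069302 to 78083913). The values count 3' end reads over a whole gene, so exons, introns and untranslated regions are not told apart.

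The fixed gene lists were described by the median log2 ratio of their measured members (Foxp3DTR over control) and its percentile among 10000 random lists of the same size and expression. In migratory DC-like cells, genes of the response to interleukin-4, interleukin-13 and GM-CSF had a median of 1.25 (percentile 100), with 12 of 15 members above a ratio of 1. Within the 7 clusters of this class with at least 20 cells per library, where fewer members can be measured, the medians of this list lay between 0.12 and 0.90. In this list Ccl24, an eosinophil chemokine, was 4.74 and 89.6 CPM (ratio 18.9, 15.1 to 24.0), although 39.7% of its control UMIs came from 1 cell. Genes induced by interferon gamma had a median of 0.86 (percentile 100, 16 of 20 above 1). Ly6a, a surface antigen induced by interferons, led them at 2.19 and 15.7 CPM (ratio 7.18, 5.07 to 10.4). Its level was low here, from 36 and 309 UMIs, against 221 and 1355 CPM in monocyte-like cells. Whether RNA of other cells brought it was not tested. Type I interferon response genes had a median of 0.33 (percentile 100, 15 of 23 above 1), from Rtp4 at a ratio of 2.63 to Mx1 at 0.404. Within the same 7 clusters, the medians lay between 0.22 and 0.81 for interferon gamma genes. For type I interferon genes they lay between -0.42 and 0.71, so their direction differed between clusters. Inflammatory cytokine and NF-kB genes had a median of -0.48 (percentile 0; 15 of 19 below 1). Tnf was 0.318, while Il6 within this list was 4.39 (3.56 to 5.47). The MHC class II presentation list had a median of 0.36 (percentile 99.97; 12 of 14 above 1) and reached from H2-DMa at 1.74 to Ctss at 0.887. This median was -0.07 with clusters weighted alike, so its direction changed with the weight given to each cluster. MHC class I genes had a median of -0.18 (percentile 0.45).

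Costimulation and maturation genes of migratory DC-like cells had a median of 0.02 (percentile 32.1), with 7 members above and 6 below a ratio of 1, between Cd80 at 3.47 and Icosl at 0.241, and this median was 0.20 (percentile 98.8) with clusters weighted alike. DC migration and chemokine genes had a median of -0.17 (percentile 3.4), with 13 of 15 members below 1 and Ccl17 and Cxcr4 (0.454) at the ends. Immunoregulatory DC genes had a median of 0.17 (percentile 96.5), from Pdcd1lg2, the gene of the PD-1 ligand PD-L2, at 4.73 (4.18 to 5.36) to Itgb8 at 0.176 (0.123 to 0.246). Glycolysis genes had a median of 0.21 (percentile 98.8), oxidative phosphorylation genes 0.11 (percentile 71.1), cell cycle genes 0.10 (percentile 93.6) and mitochondrially encoded genes -0.20 (percentile 1.59). Weighting clusters alike gave 0.12 (93.8) for glycolysis and 0.20 (99.7) for cell cycle genes, and thinning -0.20 (1.14) for DC migration and chemokine genes and -0.15 (3.08) for mitochondrially encoded genes, with percentiles in parentheses. The regulatory T cell list had 4 measured members and a median of -0.10 (percentile 30.8). Immediate early and heat shock genes, which respond to cell handling as well as to signals, had a median of -0.70 (percentile 0; 16 of 17 below 1), with Egr1 at 0.251. The median log2 ratio of all measured genes in this class was -0.05. With clusters weighted alike the log2 ratio of Ccl24 was 3.04 in place of 4.24, of Pdcd1lg2 1.58 in place of 2.24, of Il6 1.49 in place of 2.14, of Tnf -0.87 in place of -1.65, of Egr1 -1.33 in place of -2.00 and of Itgb8 -0.97 in place of -2.51, while that of Ly6a was 2.07 in place of 2.84 at a lower clustering resolution.

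In cDC2-like cells (534 control and 482 Foxp3DTR cells), Ifi205 and Ly6a, both inducible by interferons, stood highest within the limits for named genes. Plet1, outside these limits, had a log2 ratio of 4.50, the same as Ifi205. Ifi205 was 5.59 CPM in the control and 127 CPM in the Foxp3DTR library (ratio 22.7, 14.3 to 38.0). Ly6a was 24.1 and 432 CPM (ratio 17.9, 14.4 to 22.7). The larger cDC2-like cluster held 1521 of the 1557 Foxp3DTR UMIs of Ly6a and 442 of the 456 of Ifi205. In the control it held 48 of 82 and 18 of 19. These class values thus mainly describe that cluster. Rtp4 (4.09), Ifi47 (3.90), the nucleic acid sensor Zbp1 (3.88) and the transcription factor Irf7 (3.73) followed, together with Tarm1 (3.95), Ly6i (3.72) and Ffar2 (3.65). Ccl17 was 36.5 and 137 CPM (ratio 3.74, 3.07 to 4.597), and 38.7% of its control UMIs came from 1 cell. Its ratio was 12.1 in the larger cDC2-like cluster (led by Cd209a and Mmp12) and 0.695 in the smaller (led by Cd209d and Cyp7b1). In the smaller, 51.6% of the control UMIs came from 1 cell, and without the top cell of each library the ratio was 1.14 (0.729 to 1.77), so the lower value there rested on that cell. In the larger it was 17.2 (10.7 to 29.3) without the top cells. At lower and higher clustering resolution the log2 ratio of Ccl17 was 4.32 and 3.45, against 1.91 here. The Foxp3DTR level was 5.47% of that in migratory DC-like cells, while 12 other migratory DC markers stood at a median of 24.4% and Ccl22, not among these 12, at 4.14%.

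Among the genes lower in Foxp3DTR cDC2-like cells, the lysozyme genes Lyz1 and Lyz2 were 2051 and 7671 CPM in the control and 91.6 and 1336 CPM in the Foxp3DTR library (ratios 0.0446 and 0.174). Their sequences are close to each other, so the split of reads between them is uncertain. The chemokine genes Ccl9 (0.0679), Cxcl2 (0.137) and Ccl6 (0.182), the lipase gene Lpl (0.0707), the elastase gene Mmp12 (0.106), the chemokine receptor gene Ccr2 (0.191), Clu (0.143) and Klf2 (0.245) were also lower. In the larger cluster Lyz2 was 10911 and 1562 CPM and Lyz1 2960 and 111 CPM, while in the smaller Lyz2 was 392 and 613 CPM. Clu had its higher level in the smaller cluster (414 and 57.02 CPM), and Ccl9, Ccr2 and Cxcl2 were lower in both. After cDC2 markers (score 0.913), the larger cluster scored highest for monocyte markers (0.219), so these values do not separate a difference within cDC2 from a difference in the cells grouped with them. Another setting kept only cells with at least 1000 genes and at most 5% mitochondrial UMIs, and clustered and named them anew. The cells of the class could thus change along with the filter. There several log2 ratios came closer to 0: Lyz1 from -4.49 to -0.56, Mmp12 from -3.24 to -0.68, Ccl6 from -2.46 to -0.49, Lpl from -3.82 to -1.49, Cxcl2 from -2.87 to -1.83, Ccr2 from -2.39 to -1.59, Ccl9 from -3.88 to -3.04 and Lyz2 from -2.52 to -1.004. Without the top cell of each library, Lyz1 was at -5.40. Clu went from -2.81 to -0.85 at a higher clustering resolution.

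Across lists, cDC2-like cells had medians of 1.40 for interferon gamma response genes (percentile 100; 19 of 19 above 1) and 1.26 for type I interferon response genes (percentile 100; 23 of 24 above 1). These medians were 1.74 and 1.29 in the cluster led by Cd209a and Mmp12, and 0.37 and 0.27 in that led by Cd209d and Cyp7b1. MHC class I genes had a median of 0.58 (percentile 100; 16 of 18 above 1), with the immunoproteasome gene Psmb9 at 2.06 (1.92 to 2.21). MHC class II genes had a median of -0.23 (percentile 0.15; 10 of 14 below 1), with the protease gene Ctss at 0.658. Inflammatory cytokine and NF-kB genes had a median of -0.77 (percentile 0), although Il6 was 7.94 and 80.7 CPM (ratio 10.2, 6.85 to 15.7). DC migration and chemokine genes had a median of -0.45 (percentile 0.01). The interleukin-4, interleukin-13 and GM-CSF list had a median of 0.47 (percentile 99.6), which was 0.15 (percentile 56.2) after all cells were thinned to the same number of UMIs. Cell cycle genes had a median of 0.42 (percentile 99.5), oxidative phosphorylation genes 0.32 (99.2), glycolysis genes 0.25 (88), mitochondrially encoded genes -0.21 (0.52), costimulation genes -0.05 (7.02) and immunoregulatory genes 0.11 (38.1), with percentiles in parentheses. The cell cycle median was 0.69 in the cluster led by Cd209a and -0.33 in that led by Cd209d, and 0.28 (percentile 82.1) at a higher clustering resolution. The regulatory T cell list had 3 measured members and a median of 0.66 (percentile 97.9), which was 0.005 after thinning; its top member, Tnfrsf4, had a log2 ratio of 0.81 that was -0.75 at a higher clustering resolution. Immediate early and heat shock genes had a median of -0.68 (percentile 0), with 17 of 17 members below 1.

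In cDC1-like cells (165 control and 149 Foxp3DTR cells), Ly6a was 53.0 and 245 CPM (ratio 4.63, 3.71 to 5.84) and Zbp1 47.0 and 156 CPM (ratio 3.32, 2.59 to 4.28). S100a10 (3.54), the cell cycle inhibitor gene Cdkn1a (2.83), the mitotic genes Ccnb2 (2.72) and Ube2c (2.56), the sterol synthesis gene Fdps (2.68), Serpina3g (2.67) and Lgals1 (2.47) were also among the 10 highest within the limits for named genes. The neutrophil elastase gene Elane had 0 UMIs in the control and 314 in the Foxp3DTR library, at least 111-fold higher against a floor of 3 UMIs over the class, but 99.7% of them came from 1 cell. Its counting interval starts at 89.5, and the log2 bound of 6.79 was 4.45 after thinning. The tetraspanin gene Cd81 was 523 and 131 CPM (ratio 0.251, 0.216 to 0.290). Serinc3 (0.331), the orphan nuclear receptor genes Nr4a1 (0.352) and Nr4a2 (0.377), Klf4 (0.373), Ccl2 (0.373), Cd180 (0.406), Skil (0.467), the interferon gamma receptor gene Ifngr1 (0.468) and Tmem176b (0.480) were lower as well. The log2 ratio of Ccnb2 was 1.44 here and 2.64 after thinning, that of S100a10 1.82 and 2.41, and that of Cdkn1a was 1.498 and, with predicted doublets kept, 0.77.

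The lists in cDC1-like cells had medians of 0.99 for the interferon gamma response (percentile 100; 15 of 16 above 1, with the GTPase gene Iigp1 at 8.19, 4.85 to 14.8) and 0.71 for the type I interferon response (percentile 100; 14 of 17). The interleukin-4, interleukin-13 and GM-CSF list had a median of 0.88 (percentile 99.99; 8 of 9), which was 0.39 (percentile 79.6) with 5 measured members after thinning. Its top member, Ccl17, was 4.37 and 79.7 CPM (ratio 18.2, 9 to 43.1), with 65.9% of the Foxp3DTR UMIs from 1 cell; without the top cell its log2 ratio was 2.83 in place of 4.19. Inflammatory cytokine and NF-kB genes had a median of -0.60 (percentile 0), with Cxcl2 at 0.0865 from 9 Foxp3DTR UMIs, 44.4% of them from 1 cell, and MHC class II genes -0.19 (percentile 0.14). Oxidative phosphorylation genes had a median of 0.30 (percentile 99.8), glycolysis genes 0.31 (97.6), cell cycle genes 0.29 (96.2), MHC class I genes 0.16 (77.9), immunoregulatory genes 0.10 (34.9) and mitochondrially encoded genes 0.09 (54.3). After thinning, the cell cycle median was 0.83 (percentile 100) and that of MHC class I genes 0.33 (percentile 99.3). Costimulation genes (-0.12, percentile 1.72) and DC migration and chemokine genes (-0.12, percentile 1.43) had medians of 0.11 and 0.06 after thinning, so their direction changed with thinning. Immediate early and heat shock genes had a median of -0.41 (percentile 0). The log2 ratio of Cxcl2 was -3.53 here and -2.43 after thinning, its value nearest to 0 among the alternatives. The regulatory T cell list had 2 measured members here, too few for a median.

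In monocyte-like cells (293 control and 734 Foxp3DTR cells), 3 members of the interleukin-4, interleukin-13 and GM-CSF list stood highest within the limits for named genes. Ccl17 was 4.27 and 489 CPM (ratio 114, 52.5 to 312), in 6 control and 186 Foxp3DTR cells with a UMI; Foxp3DTR macrophage-like cells, given as background, had 24.1 CPM. Retnla had 0 UMIs in the control and 1078 in the Foxp3DTR library, at least 102-fold higher against a floor of 3 UMIs over the class, in 23 cells with 31.7% of UMIs from 1 cell. Plet1 had 0 and 617 UMIs, at least 58.6-fold higher against the same floor, in 45 cells. The counting intervals of these ratios start at 83.1 for Retnla and 47.5 for Plet1. All UMIs of both genes lay in the cluster led by Ms4a6d, which held 42 control cells. Within that cluster the intervals start at 15.5 for Retnla and 8.88 for Plet1. On the log2 scale the bound for Plet1 was 5.87 here, 5.11 as a mean over cells and 4.40 after thinning. Ccl24 was 66.2 and 493 CPM, with 98.9% of its control UMIs from 1 cell. The interferon-induced genes Iigp1 (12.1 and 134 CPM, ratio 11.1, 6.87 to 19.1) and Ly6a (221 and 1355 CPM, ratio 6.12, 5.46 to 6.88) were also higher, as were AA467197 (16.2), Dok2 (11.9), Tarm1 (9.82) and the chemokine gene Ccl12 (6.51). Ccl12 had a log2 ratio of 2.70 here and 0.03 with macrophage-like cells included.

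The monocyte-like class joined clusters that the libraries filled unequally. The cluster led by Ms4a6d, Klra2 and Ly6i held 42 control and 681 Foxp3DTR cells. The cluster led by Hp, Chil3 and Gm9733 also carried markers of patrolling monocytes such as Ace, and held 255 and 56 cells. Ccl17 was 8.06 and 515 CPM in the former, from 2 and 2401 UMIs, and 3.37 and 28.3 CPM in the latter. Genes lower in the Foxp3DTR library included those known from patrolling monocytes: Cx3cr1, the fractalkine receptor gene (170 and 14.8 CPM, ratio 0.0874, 0.0663 to 0.114), Eno3 (0.139), Nr4a1 (0.166) and Adgre4 (0.182). Nr4a1 was also lower in cDC1-like cells (0.352) and within the cluster led by Ms4a6d (0.279, 0.203 to 0.391). Its lower value is therefore not particular to patrolling monocytes. Hpgd (0.0855), Thbs1 (0.149), Cebpb (0.197), Apoe (0.201), Clec4b1 (0.225) and Stap1 (0.228) were lower too. With clusters weighted alike, the log2 ratio of Cx3cr1 was -2.49 in place of -3.52, of Hpgd -1.63 in place of -3.55, of Eno3 -1.16 in place of -2.85, of Nr4a1 -1.35 in place of -2.59, of Ly6a 1.06 in place of 2.61, of Iigp1 1.71 in place of 3.47, of Dok2 1.97 in place of 3.57, of Ccl24 0.51 in place of 2.90 and of Ccl17 5.79 in place of 6.84. Without the top cell of each library the log2 ratio was 7.72 for Ccl24 and 4.34 for Iigp1, and after thinning it was 4.28 for Iigp1. Weighting clusters alike gave -1.56 for Adgre4 and Thbs1, -1.17 for Stap1 and 2.54 for Tarm1. Joining macrophage-like cells gave -1.16 for Apoe, and stricter cell filtering gave 2.84 for AA467197, whose log2 ratio was 4.01.

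In the same cells the interleukin-4, interleukin-13 and GM-CSF list had a median of 1.81 (percentile 100; 17 of 17 above 1), which was 1.19 with clusters weighted alike. It was 0.77 within the cluster led by Ms4a6d and 0.58 within that led by Hp. The interferon gamma response list had a median of 1.27 (percentile 100; 19 of 19), which was 0.37 (percentile 99.2) with clusters weighted alike. Within the cluster that held most Foxp3DTR cells, led by Ms4a6d, it was -0.01, against -0.14 for all measured genes, and within that led by Hp it was 2.14. Glycolysis genes had a median of 0.82 (percentile 100; 13 of 14), with Pfkp, a phosphofructokinase gene, at 3.65 (2.80 to 4.84), and oxidative phosphorylation genes 0.52 (percentile 99.9; 19 of 19). MHC class I genes had a median of 0.51 (percentile 99.8), which was 0.20 (percentile 82.5) with clusters weighted alike. The type I interferon response list had a median of 0.34 (percentile 98.9; 20 of 24 above 1), with Isg15 at 2.72 (2.49 to 2.96), and this median was -0.29 with clusters weighted alike. It was -0.947 within the cluster led by Ms4a6d and 1.445 within that led by Hp. Inflammatory cytokine and NF-kB genes had a median of -0.36 (percentile 0.02), from Il12b at 5.79 to Ccl3 at 0.318, and 47.5% of the Foxp3DTR UMIs of Il12b came from 1 cell. The log2 ratio of Il12b was 2.53, and 0.97 with predicted doublets kept, 1.17 after thinning, 1.48 under stricter cell filters and 1.43 when clustered without the listed and named genes. Weighting clusters alike gave Isg15 a log2 ratio of 0.31 in place of 1.44 and that of Ccl3 -0.62 in place of -1.65. Costimulation genes, with Cd83 at a ratio of 0.370, had a median of -0.30 (percentile 1.59), which was -0.14 (percentile 8.04) after thinning and -0.175 (percentile 5.42) with members of at least 100 UMIs. The median was -0.30 (percentile 0.45) for DC migration and chemokine genes. Immunoregulatory genes had a median of 0.23 (82.8), which was 0.47 (97.7) after thinning, mitochondrially encoded genes 0.13 (65.4) and MHC class II genes -0.01 (22.0), with percentiles in parentheses. Cell cycle genes had a median of -0.08 (percentile 20.2), which was 0.57 with clusters weighted alike. Immediate early and heat shock genes had a median of -0.56 (percentile 0), although Ier3 was 2.04 (1.64 to 2.56). The regulatory T cell list had 2 measured members.

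**Figure D2:**
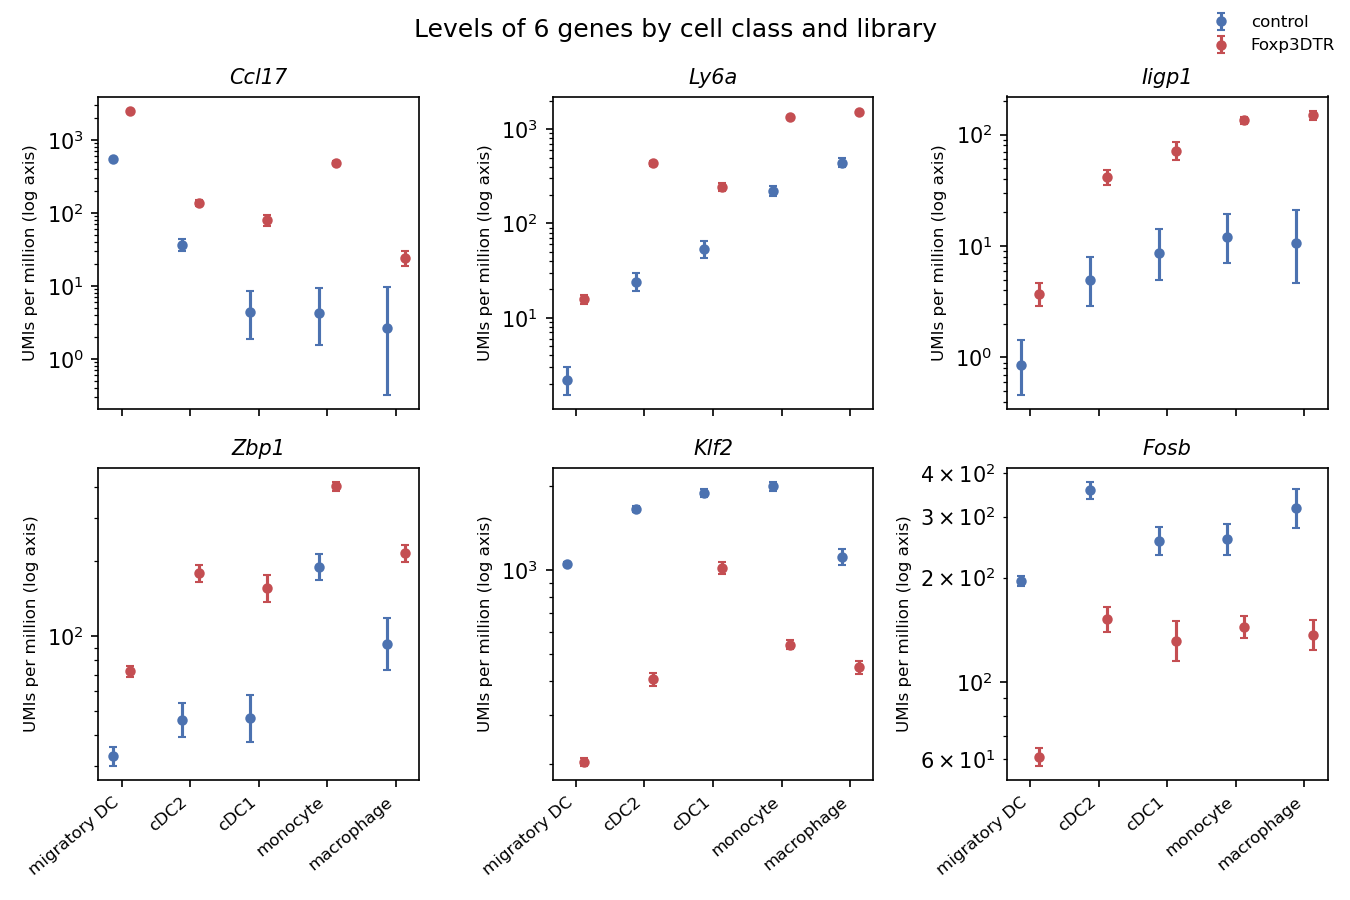
Levels of 6 genes (CPM, log axis) in 5 cell classes of the control and the Foxp3DTR library, with points for class totals and error bars for 95% counting intervals. Ccl17 in monocyte-like cells was 4.27 and 489 CPM, and Klf2 in migratory DC-like cells 1051 and 205 CPM.

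**Figure D3:**
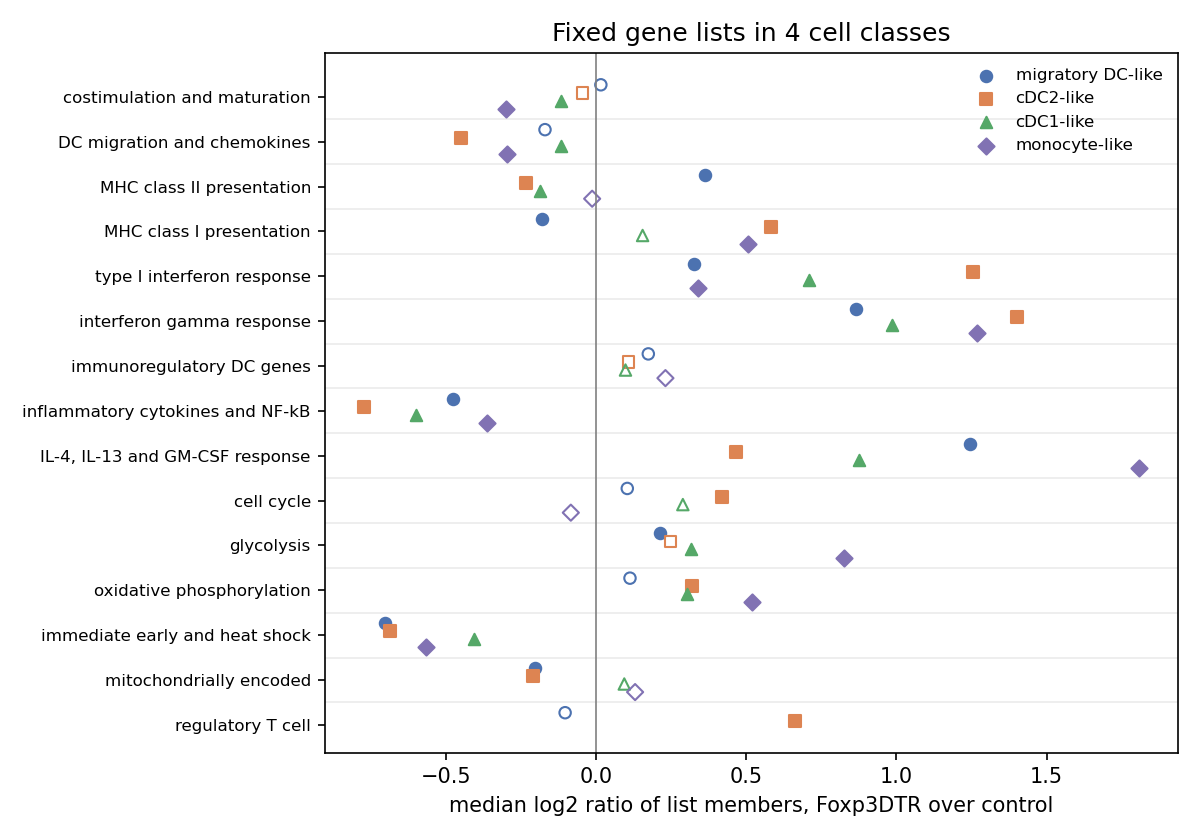
Median log2 ratio (Foxp3DTR over control) of each gene list in the 4 compared classes, with filled markers for medians outside the central 95% of random lists and open markers for those inside. Interferon gamma response genes lay between 0.86 and 1.40 in the 4 classes, and immediate early and heat shock genes between -0.70 and -0.41.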

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

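The tests in this part were all chosen after the results they bear on had been seen.

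MHC presentation genes were singled out because the classes moved in opposite directions. MHC class II genes had a median log2 ratio of 0.36 in migratory DC-like cells, -0.23 in cDC2-like cells and -0.19 in cDC1-like cells. MHC class I genes had a median of -0.18 in migratory DC-like cells, 0.58 in cDC2-like cells and 0.51 in monocyte-like cells. The differences between classes were not tested, since there was 1 library per genotype. With clusters weighted alike, the class II median in migratory DC-like cells was -0.07 and the class I median in monocyte-like cells 0.20 (percentile 82.5), inside the random lists.

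Ccl17 was higher in the Foxp3DTR library in the 4 compared classes, and in monocyte-like cells it stood at 19.6% of its migratory DC level against a median of 6.51% for 12 other migratory DC markers (Ccl22 left out), a ratio of 3.01 (2.89 to 3.13, for the counts of Ccl17 alone). These markers reached from 2.49% (Fscn1) to 27.2% (Cd63), but RNA from migratory DCs would bring all of them, so the low Fscn1, and Ccl22 at 2.72%, argue against such RNA as the whole source. Foxp3DTR monocyte-like cells with Ccl17 had an Mgl2 UMI more often than those without (44.3% and 13.3%, thinned) and a Ly6c2 UMI less often (32.1% and 52%). Whether the Ccl17 came from monocytes or from other cells grouped with them was not settled. In cDC2-like cells the ratio of Ccl17 to the median of the 12 markers was 0.224 (0.204 to 0.244). It decides nothing, since markers such as Il4i1 (101%) stood at levels that migratory DC RNA could not bring. Ccl22, at 4.14%, bounds what such RNA could bring and lies under the Ccl17 fraction of 5.47%. Such RNA is therefore possible, but not shown, as a source of part of the Ccl17. In Foxp3DTR macrophage-like cells Ccl17 stood at 0.96%. In cDC1-like cells the ratio was 0.909 (0.763 to 1.07), which decides nothing because 1 cell held most UMIs. A different mix of migratory DC clusters is argued against by a log2 ratio of 2.49 with clusters weighted alike, against 2.19 without, and by a Ccl17 ratio of 5.10 within the cluster that this weighting left out (15 control cells). Loss of regulatory T cells after DTx stays open, and with 1 library per genotype it cannot be told apart from other differences between the animals.

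Monocyte-like and macrophage-like cells, joined into a single group, were 9% of control cells (387) and 20.8% of Foxp3DTR cells (1045), a ratio of 2.31 (1.99 to 2.69). A loss of dendritic cells at an unchanged number of all other cells would raise every other class alike, but basophil or mast cell-like cells had a ratio of 0.519 (0.24 to 1.1), which argues against it. The choice of filters and clustering is also argued against as the cause, since the lowest ratio over 8 alternatives was 2.31 and the highest 2.43. All 8 named clusters by the same marker lists, so they do not test the naming. The larger cDC2-like cluster (392 control and 378 Foxp3DTR cells) scored second for monocyte markers and had Lyz2 at 10911 and 1562 CPM. The monocyte-like cluster led by Ms4a6d (42 control and 681 Foxp3DTR cells) had 0 monocyte markers among its 10 leading genes. That led by Hp went the other way, with 255 and 56 cells. The naming therefore stays open. A difference between the sorts or the animals stays open and cannot be told apart from the genotype, with 1 library of each.

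Immediate early and heat shock genes were lower in the Foxp3DTR library in the 4 compared classes. Their median lay below that of all measured genes in 17 of 17 clusters with at least 20 cells per library, as cell handling that differed between the libraries would give. The deeper Foxp3DTR library is argued against as the cause, because the median in migratory DC-like cells was -0.69 with cells thinned to 3000 UMIs, against -0.70 at full depth. Loss of regulatory T cells stays open too, and with 1 library per genotype it cannot be told apart from handling.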

How the results depend on the processing

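The alternatives that weighted clusters alike, clustered without the listed and named genes, joined monocyte-like and macrophage-like cells or left out a gene's top cell were chosen after the data had been seen. Of the share ratios under alternatives, 44 of 47 stayed within their interval and 3 moved; of the list medians, 540 of 591 kept their direction and their side of the random lists, 19 came to lie beyond them, 26 no longer did, 1 moved and 5 reversed; of the gene ratios, 1779 of 2063 stayed within their interval, 275 moved and 9 reversed; and 12 of 12 depth values stayed close. The causes of the changes were not tested, except that thinning lowers the counts by construction. No paired analysis was possible because there was 1 library per genotype. At Leiden resolution 0.5 the macrophage-like class merged with others and gave no value of its own. On simulated data, 150 cells per library recovered fewer changes than 3000 did.

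Share ratios were 0.918 for migratory DC-like and 0.956 for cDC2-like cells with each library clustered on its own, and 0.931 for cDC2-like cells at resolution 0.5. The following are median log2 ratios. With clusters weighted alike, migratory DC-like cells had 0.200 for costimulation, -0.071 for MHC class II (reversed), 0.197 for cell cycle and 0.116 for glycolysis; monocyte-like cells had 0.203 for MHC class I, -0.287 for type I interferon (reversed) and 0.570 for cell cycle. At resolution 0.5, migratory DC-like cells had -0.193 for migration and chemokines, 0.093 for MHC class II, 0.199 for immunoregulation and 0.170 for glycolysis, cDC2-like cells had 0.328 for oxidative phosphorylation and cDC1-like cells 0.322 for glycolysis. At resolution 2, migratory DC-like cells had -0.199 for migration and 0.181 for immunoregulation, cDC2-like cells 0.277 for cell cycle, and cDC1-like cells -0.087 for costimulation and 0.037 for migration (reversed).

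With cells thinned, migratory DC-like cells had -0.204 for migration, 0.193 for glycolysis and -0.152 for mitochondrially encoded genes. In cDC2-like cells, thinning gave 0.154 for interleukin-4, interleukin-13 and GM-CSF and 0.005 for regulatory T cell genes. In cDC1-like cells it gave 0.105 for costimulation (reversed), 0.061 for migration (reversed), 0.330 for MHC class I, 0.385 for interleukin-4, interleukin-13 and GM-CSF and 0.829 for cell cycle. In monocyte-like cells it gave -0.142 for costimulation and 0.466 for immunoregulation. As a mean over cells, migratory DC-like cells had -0.268 for migration, 0.202 for immunoregulation and 0.213 for cell cycle, cDC2-like cells 0.575 for regulatory T cell genes, and cDC1-like cells -0.084 for costimulation and 0.390 for cell cycle.

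With members of at least 5 UMIs, migratory DC-like cells had 0.192 for immunoregulation and 0.242 for cell cycle, and cDC2-like cells 0.321 for regulatory T cell genes. With members of at least 100 UMIs, migratory DC-like cells had -0.163 for migration, cDC1-like cells -0.014 for costimulation, -0.034 for migration, 0.208 for MHC class I and 0.315 for glycolysis, and monocyte-like cells -0.175 for costimulation. With predicted doublets kept, cell cycle was 0.25 in migratory DC-like cells, interleukin-4, interleukin-13 and GM-CSF 0.366 in cDC2-like cells and costimulation -0.055 in cDC1-like cells. Clustering without the listed and named genes gave 0.341 for interleukin-4, interleukin-13 and GM-CSF and 0.506 for regulatory T cell genes in cDC2-like cells, and -0.067 for costimulation in cDC1-like cells.

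Among genes whose interval excluded a ratio of 1, the reversed values, as log2 ratios, were those of mt-Atp6 in migratory DC-like cells (-0.013 as a mean over cells, -0.017 with clusters weighted alike) and in cDC2-like cells (-0.009 with centred ratios), Tnfrsf4 in cDC2-like cells (-0.748 at resolution 2), Cxcl10 (0.152) and Rrm2 (0.474) in thinned cDC1-like cells, Ccl6 in cDC1-like cells (0.124 with at least 1000 genes and at most 5% mitochondrial UMIs), and Cd40 (-0.181) and Cd274 (-0.029) in monocyte-like cells with clusters weighted alike. Some genes whose interval included 1 changed sign too, among them Retnla in migratory DC-like cells (-0.31; 0.66 as a mean over cells, but -2.38 after thinning, -1.59 with clusters weighted alike and -1.57 without the top cell) and Mx1 in cDC1-like cells (-0.76, and 0.57 after thinning).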

Other observations

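The groups and values in this part were all chosen after the data had been seen. Macrophage-like cells, with 94 control cells too few for the comparisons above, had Iigp1 at 10.7 CPM in the control and 149 CPM in the Foxp3DTR library (ratio 13.9, 7.01 to 32.5). Ly6a was 442 and 1522 CPM (ratio 3.44, 3.08 to 3.86), Fgl2 had a ratio of 3.42 and the chemokine gene Ccl8 one of 2.56. Serinc3 (0.230), Ccl2 (0.258) and Sepp1, a selenium transport protein gene (0.324), were lower. The interferon gamma response list had a median log2 ratio of 0.90 there, and immediate early and heat shock genes one of -0.66. Over the clusters with at least 20 cells per library, the interferon gamma response list lay above all measured genes in 16 of 17, the interleukin-4, interleukin-13 and GM-CSF list above in 16 of 17, and the inflammatory cytokine and NF-kB list below in 16 of 17.

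Among Foxp3DTR monocyte-like cells thinned to 3000 UMIs (51 shallower cells left out), Mgl2, a lectin gene of type 2 DCs and alternatively activated macrophages, had a UMI in 44.3% of 106 cells with Ccl17 (34.7% to 54.3%) and in 13.3% of 577 cells without (10.7% to 16.4%). Plet1 had a UMI in 17% and 2.6%, and Ccl24 in 29.2% and 12.1%. Ly6c2, a marker of classical monocytes, had a UMI in 32.1% and 52%. The migratory DC markers Fscn1 (21.7% and 22.7%) and Ccr7 (24.5% and 23.6%) did not separate the cells in this way. An unnamed cluster led by Esam and Asprv1 (93 control and 152 Foxp3DTR cells) had Ccl17 at 2.39 CPM in the control, from 1 UMI, and 404 CPM in the Foxp3DTR library, where 70.3% of the UMIs came from 1 cell (120 CPM without it). An unnamed cluster led by cycling genes such as Birc5 and Nusap1 held 24 control and 72 Foxp3DTR cells.

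Over all cells used, several but not all marker lists of cell types outside the compared classes also differed. These sums include UMIs from cells of the compared classes, so they do not measure numbers of the cell types. Il1r2 of the neutrophil list, for example, was 103 and 31.4 CPM in the cDC2-like cluster led by Cd209d, control first. Only 4 control and 3 Foxp3DTR cells passed the neutrophil marker limit. Langerhans cell markers were 364 and 114 CPM, eosinophil markers 15.1 and 1.34 CPM, neutrophil markers 471 and 229 CPM, patrolling monocyte markers 536 and 264 CPM and stromal or endothelial markers 551 and 109 CPM, control first. Classical monocyte markers were 699 and 1263 CPM and macrophage markers 1347 and 2318 CPM. Migratory DC markers were 16038 and 15302 CPM, cDC2 markers 460 and 495 CPM, cDC1 markers 1180 and 1357 CPM and plasmacytoid DC markers 328 and 326 CPM. Basophil or mast cell markers were 118 and 66.9 CPM. T cell markers were 27.9 and 24.2 CPM, B cell markers 30.3 and 25.2 CPM, plasma cell markers 40.5 and 37.4 CPM and markers of NK or innate lymphoid cells 107 and 110 CPM, in cells sorted to lack CD90.2, B220 and NK1.1. Melanoma cell markers were 1.56 and 0.200 CPM and erythroid markers 0.998 and 0.171 CPM.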
